A study of Homo sapiens with 10 samples.

How the data were processed

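ChIP-seq libraries from SK-N-SH cells were analysed from the peak lists that the authors deposited, 1 list per library. The cells were kept in medium with charcoal-stripped serum for 24 hours before treatment and then received 1 µM retinoic acid (RA) or vehicle (UT), per the labels' protocols. The labels name 10 samples. Of these, 8 are immunoprecipitates with an antibody against MAML3 or RARα, 2 replicates for each antibody and treatment, and 2 are input samples, which were not analysed here. Groups and replicate numbers came from the labels.

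Libraries were amplified for 15 cycles and sequenced on the Genome Analyzer, per the labels' protocols. The submitters' processing notes name BWA 0.5.9, MACS and bedtools, with no version for the last 2, and the hg19 build, without saying which step used which setting. Each sample has its own list, per the labels. The list name of RARα UT replicate 2 carries a tag for merged data in place of a lane, which no label explains, so whether this shortest list stands for 1 library is not known. Whether an input entered the call, the threshold, and the list used for the filtering and intersection that the list names mention are not given in the sources used here. Each deposited list gives a chromosome, a start, an end, a peak name and 1 number per peak, with no header. That number is treated here as a score that the authors deposited, with a minimum of about 70 in each list and a ceiling of 3100 for most of the highest peaks. It was used to rank peaks within a list and to shorten lists, never to compare levels between libraries. The peak names are numbered, and some numbers are not listed, from 2.86% of them in MAML3 RA replicate 1 to 35.1% in RARα UT replicate 2, so peaks with those numbers were not analysed here. Nearly all widths in the 2 MAML3 RA lists were multiples of 50 bp (99.9 and 100%), against 23.8 and 66.6% in the MAML3 UT lists and 20.7 to 38.1% in the RARα lists, so peak edges were resolved differently between lists. The list names carry lane tags, by which MAML3 UT 1 and RA 2 share a lane number, as do UT 2 and RA 1. The crossed split of the MAML3 libraries is therefore also the split by lane number. The 2 MAML3 UT lists carry the same library number and index tag, unlike the 2 RA lists, so they may come from 1 library sequenced on 2 lanes, which no label states. Their peak numbers differed 3.04 times, and they were kept as 2 libraries.

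Peaks of the 4 libraries of an antibody that overlapped by 1 bp or more were merged into sites, and a site belonged to a library when a peak of that library was part of it. A site was gained when both RA libraries and neither UT library held it, and lost in the opposite case. These counts come with no p-value, and stand beside the counts for the other 2 of the 3 splits of the 4 libraries into pairs. Overlap between lists was the share of the shorter list, or of the RARα sites held by both replicates, that overlapped by 1 bp or more. It was tested, one-sided, against 1000 random relocations on the same chromosome within the range where any list had peaks, with random seed 11. Shares have 95% Wilson intervals, which cover counting error only. Lists were also compared at equal length, by keeping the 2222 (MAML3) or 251 (RARα) peaks with the highest score. Shares of one set of sites on 2 lists were compared with the exact McNemar test and shares of 2 sets of sites with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Gained sites within 500 kb of each other were counted against 1000 random draws of as many sites. Read depth is not given in the sources used here, so no precision could be set from it. A short list can come from a shallow library, and a site absent from a list is not shown to be unbound.

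The sites named in the text were fixed by a rule before the data were examined. For each antibody they are up to 10 gained and 10 lost sites and the 10 highest ranked sites in all 4 libraries, ranked by the mean score percentile over the libraries that hold them, and the 10 highest ranked sites with all 4 MAML3 libraries and both RARα libraries of a treatment. The text gives some of each set. Dense regions, clusters of gained sites, sites in all 8 lists and RARα sites without MAML3 were chosen after the data were seen. The annotation at hand was on another build than hg19. The planned share of sites at promoters, the gene lists with their enrichment test, the motif shares and the genes named in the rule were therefore not run, and sites have no gene names.

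The alternatives were a stricter overlap of 50% of the shorter peak, a looser one of 1 kb, the 50% of peaks with the highest score, lists of equal length, sites in at least 1 replicate, and each replicate left out in turn. For the number of peaks per list, chromosome Y was also left out. Added after the data were seen were a shift of each RARα site by 10 to 100 kb and the removal of sites in the outer 100 kb of each chromosome. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting was tested on simulated lists. All 610 planted gained and 516 planted lost sites of 7685 simulated MAML3 sites were recovered, as were all 146 and 125 of 1821 simulated RARα sites. These planted sites stood far apart, were not narrow and moved little between lists, so full recovery was bound to follow. Calling among close or narrow peaks, which the deposited lists hold, was not tested. A planted overlap of 39.6% of 187 sites was recovered as 39.6%, and 1 of 39.9% of 556 sites as 40.0%. Of 40 lists without planted overlap, 0 (UT sizes) and 3 (RA sizes) had p under 0.05.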

Results

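Genome occupancy of MAML3 and of the retinoic acid receptor RARα was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in SK-N-SH, an established human neuroblastoma cell line. MAML3 is a mastermind-like transcriptional coactivator, and RARα is a nuclear receptor that binds retinoic acid. The cells received either vehicle (untreated, UT) or 1 µM retinoic acid (RA). Each antibody was used in 2 libraries per treatment, which gave 8 peak lists in 4 groups. The labels do not say whether the 2 replicates of a group came from separate cultures, so the spread between them may be technical. By the tags in their list names, the 2 untreated MAML3 lists may be 1 library sequenced on 2 lanes, which no label states. The list of RARα untreated replicate 2 is tagged as merged, with no label saying from what. The read depth of the libraries is not given in the sources used here, and the number of peaks per list was the only measure of how much was called. All positions are on the hg19 build and start at 1. The sites are named by position because a gene annotation of this build was not used here.

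The untreated MAML3 lists held 2222 and 6759 peaks (mean 4490.5 ± 3208, SD, n = 2), and the MAML3 lists after RA held 7532 and 6230 (mean 6881 ± 921, SD, n = 2). The RARα lists were shorter, with 1321 and 251 peaks in untreated cells (mean 786 ± 757, SD, n = 2) and 1103 and 1064 after RA (mean 1083.5 ± 27.6, SD, n = 2). For both antibodies the difference between treatments was smaller than the spread between the 2 untreated libraries. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.33, so peak numbers were not tested. The median peak width was 268 and 300 bp in the untreated MAML3 lists, 350 and 400 bp in the MAML3 lists after RA, and between 206 and 250 bp in the RARα lists. Widths were multiples of 50 bp in 99.9 and 100% of peaks in the MAML3 RA lists, against 23.8 and 66.6% in the untreated ones. Peak edges were thus resolved differently, and the MAML3 widths cannot be read as a difference between treatments.

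The 2 libraries of each group were compared first, to see how far the lists shared their positions. In untreated cells, 93.4% of the peaks in the shorter MAML3 list overlapped a peak of the longer one, and the share after RA was 79.4%. For RARα the shares were 77.3% in untreated cells and 54.0% after RA. Peaks relocated at random on their own chromosome overlapped in at most 0.209% on average over 1000 draws, and the one-sided permutation p was 0.001 for each of the 4 pairs, the smallest value 1000 draws can give. Pairs from different treatments overlapped too. With every MAML3 list shortened to its 2222 highest-scoring peaks, the untreated pair shared 73.4%, the RA pair shared 76.2% and the 4 pairs across treatments shared 63.1 to 73.9%. With every RARα list shortened to 251 peaks, the untreated pair shared 43.4%, the RA pair 62.2% and the pairs across treatments 39.0 to 55.8%.

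The 4 MAML3 lists merged into 10251 sites, of which 1724 (16.8%) were present in all 4 libraries and 3812 (37.2%) in 1 library. Among the sites in all 4, the 10 with the highest mean score percentile included 3 within a short stretch of chromosome 4, at 174851399 to 174852049, 174930600 to 174931299 and 174990899 to 174991561. Each of these 3 also carried a RARα peak in all 4 RARα lists. Chromosome 7 held 2 of the 10, at 18737696 to 18738400 and 8268297 to 8268950. Further members lay on chromosome 1 at 96371300 to 96371949, on chromosome 5 at 55792299 to 55792949 and 164005799 to 164006349, and on chromosome 14 at 36026484 to 36027071 and 89464284 to 89464994. The next stretch of chromosome 4, from 175057179 to 175181611, held 15 further MAML3 sites present in at least 3 of the 4 lists, as many as any other window of 500 kb examined.

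**Figure D1:**
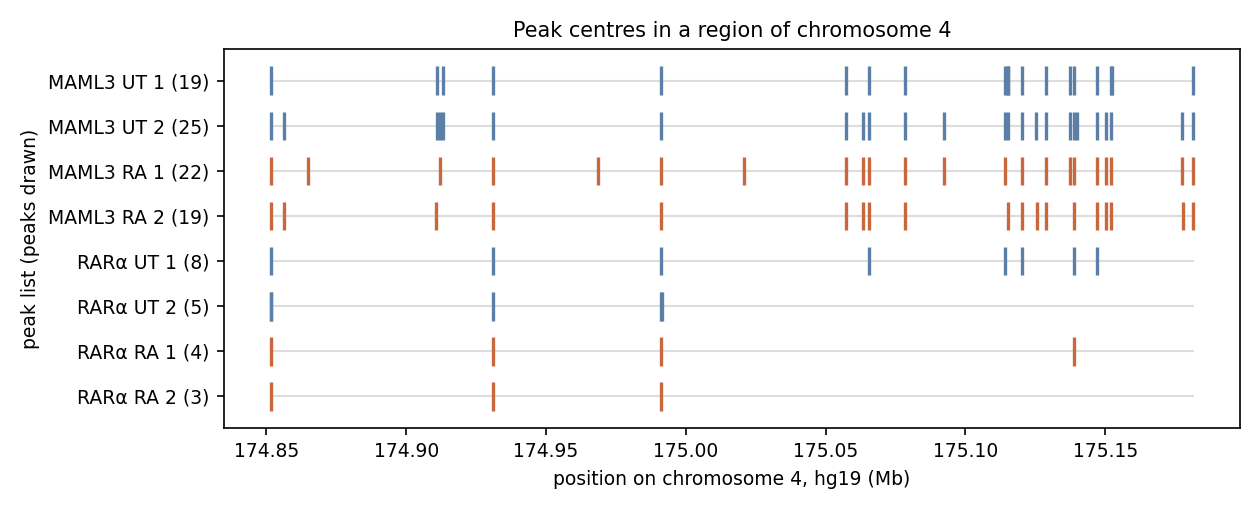
Peak centres in the 8 lists between 174851399 and 175181611 of chromosome 4, with position in Mb on the horizontal axis, a row per list, untreated lists in blue, lists after RA in orange, and the number of peaks in brackets. The 4 MAML3 lists hold 19 to 25 peaks here and the RARα lists 3 to 8, with the 3 leftmost MAML3 sites named in the text present in all 8 rows.

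The comparison of untreated with RA-treated cells addressed which MAML3 sites depended on the treatment. A site was called gained when both RA libraries and neither untreated library held it, and lost in the opposite case. There were 961 gained and 70 lost MAML3 sites. The gained sites were mostly low in the lists, with a median score percentile of 36.2 against 74.4 for the sites in all 4 libraries. The highest ranked gained sites lay on chromosome 11 at 83574363 to 83574662, on chromosome 13 at 104659098 to 104659650, on chromosome 4 at 108373812 to 108374399 and 151490562 to 151491149, on chromosome 17 at 55700301 to 55700718, and on chromosome 2 at 72775132 to 72775731. The others of the top 10 were on chromosome 14 at 61943406 to 61943933 and 54742706 to 54743433, on chromosome 18 at 57126973 to 57127572, and on chromosome 11 at 30750713 to 30751262. Of these 10 gained sites, 7 also overlapped at least 1 RARα list.

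Many lost MAML3 sites stood close to a peak of an RA list, whether or not an untreated list also held that peak. A peak of an RA list lay within 1 kb of 31 of the 70 lost sites (44.3%) and of 9 of the 10 highest ranked, whereas 25 of the 961 gained sites (2.60%), and 3 of the 10 highest ranked, had an untreated peak that close. The highest ranked lost site, on chromosome 11 at 83575482 to 83576156, was 819 bp from the highest ranked gained site. On chromosome 7 the lost site at 8269600 to 8269999 was 649 bp from a peak of an RA list, next to a site in all 4 libraries. Lost sites on chromosome 3 at 119357686 to 119358106 and on chromosome 10 at 60731932 to 60732455 were 646 and 552 bp from such a peak.

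The order of gained and lost sites depended on the short list of untreated replicate 1. Without that library 981 sites were gained and 1370 lost, a change that follows in part from the rule, since 1 library alone then decides which sites are untreated. Without untreated replicate 2 the counts were 3201 and 139, without RA replicate 1 they were 1851 and 176, and without RA replicate 2 they were 2529 and 117. With all 4 lists shortened to 2222 peaks, 289 sites were gained and 173 lost. An exact permutation p cannot fall below 0.33 with 2 libraries against 2, so the same counts were made for the other 2 ways of splitting the 4 libraries into pairs. In the full lists the treatments were parted by 1031 sites, the replicate numbers by 357 and the crossed pairs (UT 1 with RA 2, UT 2 with RA 1, which also share a lane tag) by 913. In the lists of equal length the treatments were parted by 462 sites, and the other splits by 95 and 184.

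**Figure D2:**
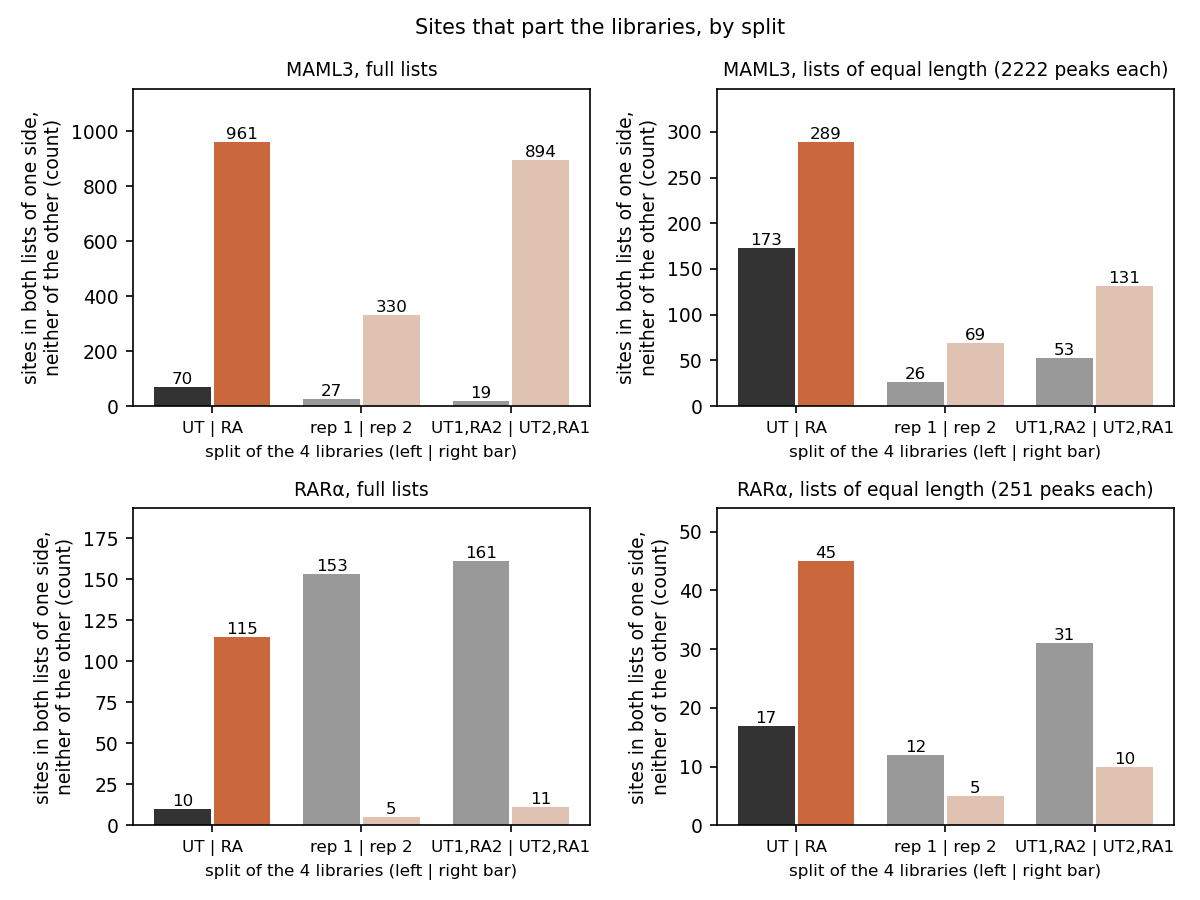
Sites held by both libraries of a side and neither of the other, as counts, for each of the 3 splits of the 4 libraries of MAML3 (top) and RARα (bottom), with the full lists on the left and lists of equal length on the right. In the full MAML3 lists RA gained 961 and lost 70 sites, and in the lists of equal length 289 and 173, while the other splits parted 95 and 184 sites in total.

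RARα sites that appeared with RA included several of high rank. The 4 RARα lists merged into 2120 sites, with 143 (6.75%) in all 4 libraries and 1187 (56.0%) in 1 library. RA gained 115 sites and lost 10. The highest ranked gained sites lay on chromosome 1 at 12533895 to 12534544, 61219095 to 61219544 and 110600695 to 110601244. Chromosome 2 held 4 of the 10, at 72431471 to 72432034, 72499067 to 72499584, 72775085 to 72775684 and 166489071 to 166489484. The remaining ones were on chromosome 17 at 59142685 to 59143171, chromosome 13 at 104659105 to 104659606 and chromosome 11 at 134874386 to 134874832. Every one of these 10 overlapped a peak in at least 2 MAML3 lists. The median score percentile of the gained RARα sites was 51.3, against 78.9 for the sites in all 4 libraries. The lost sites ranked lower (median percentile 39.5), led by a site on chromosome 9 at 98979651 to 98979983, and none of the 10 had a peak of an RA list within 1 kb.

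Among the RARα sites in all 4 libraries, the 10 highest ranked included sites at the very start of chromosomes 1 (9995 to 10538), 5 (11245 to 11794) and 12 (95327 to 95753), a pair on chromosome 17 (19091235 to 19091871 and 19093112 to 19093705), and a pair on chromosome X (114987159 to 114987660 and 114993109 to 114993660). The others lay on chromosome 11 at 62608933 to 62609435, chromosome 14 at 35015893 to 35016526 and chromosome 17 at 45973185 to 45973721. The last of these had no peak in any MAML3 list. The pair on chromosome X lay in a regular array described below. In RARα UT replicate 2, 15 of the 251 peaks lay in the outer 100 kb of a chromosome's listed range and 16 in this array. Such places therefore weigh on the untreated RARα sites. The array counted as 16 separate RARα sites, and no alternative setting of the overlap or of the gained and lost counts left it out. Whether they are repeated sequence was not examined, so their rank does not show strong binding.

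In the full RARα lists the treatments were parted by 125 sites, fewer than the 158 and 172 parted by the other 2 splits, both of which set the long untreated list apart from the list of 251 peaks. With all lists shortened to 251 peaks, 45 sites were gained and 17 lost, 62 in total, and the other splits parted 17 and 41. Without untreated replicate 2, the shortest list, 125 sites were gained and 527 lost, and without untreated replicate 1 the counts were 403 and 40.

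Gained sites of both antibodies met in a stretch of chromosome 2 from 72431482 to 72922331. This stretch was picked after its values were seen, as one of the 3 windows with the most gained MAML3 sites. The RA lists held 7 and 11 MAML3 peaks and 5 and 5 RARα peaks there. The untreated lists held 0 and 1 MAML3 peaks and 1 and 0 RARα peaks. Gained MAML3 sites at 72431482 to 72432031, 72499032 to 72499681 and 72775132 to 72775731 each coincided with a gained RARα site. On chromosome 18, from 57120673 to 57478472, 9 gained MAML3 sites lay together, the most of any such window. The RA lists held 13 and 17 MAML3 peaks there against 1 and 5 in the untreated lists, and 4 and 3 RARα peaks against 0 and 0. The remaining window, on chromosome 13 from 35867648 to 36289100, had 7 gained MAML3 sites, with 12 and 14 MAML3 peaks in the RA lists against 2 and 8, and 2 and 2 RARα peaks against 1 and 0.

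**Figure D3:**
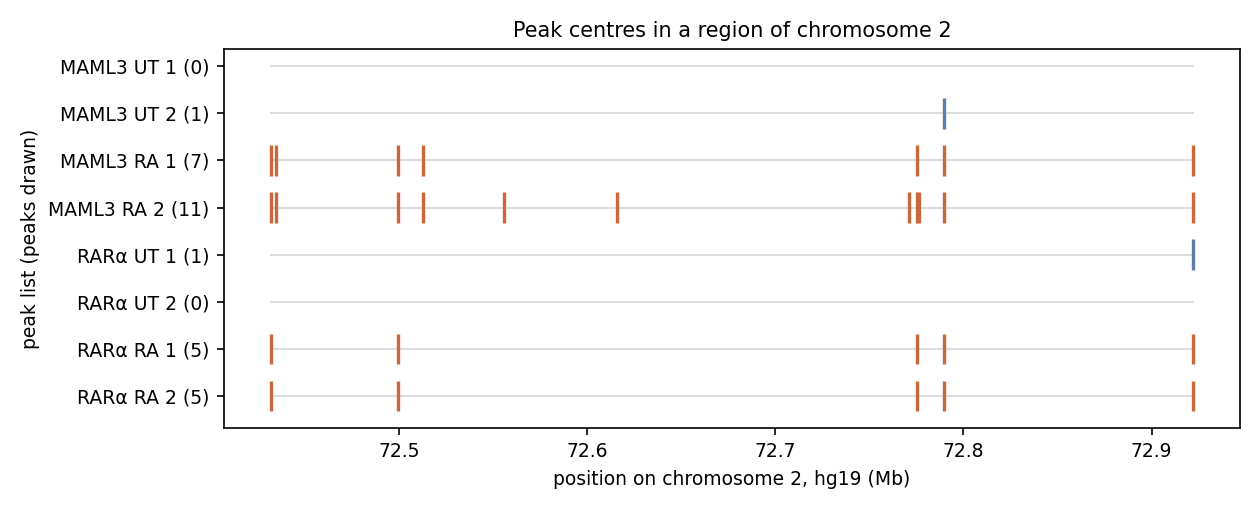
Peak centres in the 8 lists between 72431482 and 72922331 of chromosome 2, with position in Mb on the horizontal axis, a row per list, untreated lists in blue, lists after RA in orange, and the number of peaks in brackets. The RA lists hold 7 and 11 MAML3 peaks and 5 and 5 RARα peaks, and no untreated list holds more than 1.

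Whether the receptor and the coactivator lay at the same positions was asked within each treatment, over sites held by both replicates. In untreated cells 105 of 187 RARα sites (56.1%, 95% Wilson interval 49.0 to 63.1) overlapped a MAML3 site. After RA the number was 454 of 556 (81.7%, interval 78.2 to 84.7). RARα sites relocated on their chromosome overlapped in 0.0588% and 0.146% on average, and the one-sided permutation p over 1000 draws was 0.001 for both, the smallest they can give. Seen from MAML3, 5.41% of 1940 untreated sites and 9.12% of 4945 sites after RA carried a RARα site. The intervals cover counting error only, and sites of a list are not replicates. The strongest shared sites lay on chromosome 7 at 18737696 to 18738450, chromosome 20 at 35862391 to 35863009, chromosome 14 at 89451972 to 89452776, chromosome 3 at 119051436 to 119052055 and chromosome 4 at 95574249 to 95574849. All 8 lists held 73 sites, among them those on chromosome 15 at 78963957 to 78964620, chromosome 17 at 59222219 to 59222877 and chromosome 2 at 177439018 to 177439731.

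The order of the treatments depended on which sites were taken. In the 50% of peaks with the highest score the untreated share was 29.7% and the RA share 71.5%. The 187 untreated RARα sites overlapped MAML3 sites of the RA group in 67.9%, and the 556 RARα sites after RA overlapped untreated MAML3 sites in 59.4%. Over sites held by at least 1 replicate the shares were 83.4% in untreated cells and 81.8% after RA. Peak by peak, 83.4% of RARα untreated replicate 1 lay on MAML3 untreated replicate 2 and 61.2% on untreated replicate 1. For RARα untreated replicate 2 the shares were 66.1 and 56.2%. The 4 pairs of RA libraries gave 76.1 to 83.8%, above 3 of the 4 untreated pairs. With MAML3 lists of equal length this order was not kept, since the RA pairs gave 57.6 to 69.2% and the untreated pairs 42.2 to 64.0%.

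**Figure D4:**
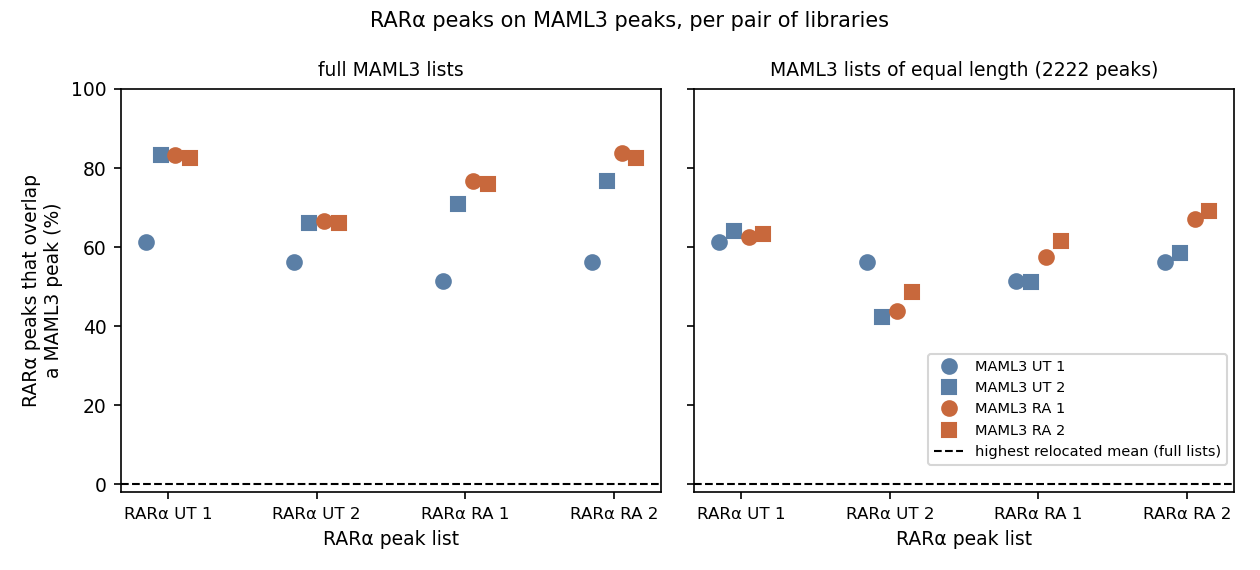
Percent of the peaks of each RARα list (horizontal axis) that overlap a peak of each MAML3 list (blue, untreated; orange, RA; circles, replicate 1; squares, replicate 2), with full MAML3 lists on the left and lists of 2222 peaks on the right. The dashed line near 0 is the highest mean over relocated peaks. In the full lists the untreated pairs lie at 56.2, 61.2, 66.1 and 83.4%, and the pairs of RA libraries span 76.1 to 83.8%.

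MAML3 sites with a high score carried RARα more often. The MAML3 sites of both replicates were ranked by score percentile and divided into 4 classes of equal size. In untreated cells the share with a RARα site was 2.89% in the lowest class and 10.1% in the highest. After RA it was 1.29% in the lowest class, 2.27 and 4.21% in the middle classes, and 28.7% (interval 26.3 to 31.3) in the highest. Of the 961 gained MAML3 sites, 43 (4.47%) carried a RARα site of both RA libraries, against 310 of the 1724 sites in all 4 libraries (18.0%, two-sided Fisher's exact p = 2.61e-26, adjusted p = 1.3e-25 over 5 such tests). The direction was not the same at matched score in the RA lists. In the lower 2 of 4 classes of RA score percentile gained sites carried RARα less often than sites in all 4 libraries, with 0.76 against 5.49% and 2.58 against 6.67% (Fisher's exact test, adjusted p = 0.011 and 0.0321). In the upper 2 classes they carried it more often, with 13 of 124 (10.5%) against 18 of 459 (3.92%) and 19 of 40 (47.5%) against 271 of 934 (29.0%, Fisher's exact test, adjusted p = 0.011 and 0.0253).

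The 115 RARα sites gained with RA lay on the RA MAML3 lists more often than on the untreated ones. With MAML3 lists of equal length, 68.7 and 71.3% of them were on the 2 RA lists, and 37.4 and 42.6% on the 2 untreated lists. Against untreated replicate 2, the exact McNemar test over sites gave two-sided p = 2.27e-07 for RA replicate 1 and p = 1.07e-06 for RA replicate 2 (Benjamini-Hochberg adjusted p = 6.49e-07 and 2.25e-06 over 40 tests). The 432 RARα sites of both RA lists that untreated replicate 1 also held, which were not gained, lay on the RA lists more often too, with 73.6 and 75.5% against 67.8 and 66.2% on the untreated lists (exact McNemar test, adjusted p at most 0.0227 in the 4 comparisons). In the full lists this difference was not detected against untreated replicate 2, with 85.9 and 85.6% against 83.6% (exact McNemar test, adjusted p = 0.204 and 0.284). The gained sites passed there too, with 83.5 and 80.0% against 67.0% (exact McNemar test, adjusted p = 0.00025 and 0.0169). Whether the 2 classes differ in this was not tested. At equal length, the 517 RARα sites held by untreated replicate 1 alone had shares of 47.0 and 45.8% on the RA lists. Their share was higher on MAML3 untreated replicate 2 (54.5%, exact McNemar p = 7.8e-05 and 7.03e-05, adjusted p = 0.00013 and 0.000128). On untreated replicate 1 it was 47.4%, with no detected difference from the RA lists (exact McNemar p = 0.928 and 0.557). In the full lists the 517 sites had 79.1 and 77.0% on the RA lists. They had 81.6% on untreated replicate 2 (exact McNemar test, adjusted p = 0.131 and 0.00421) and 47.4% on untreated replicate 1, the short list. At equal length, the 300 sites of RA replicate 2 alone lay more often on the RA lists, with 49.3 and 52.3% against 32.7 and 41.0% (exact McNemar test, adjusted p at most 0.00145). In the full lists they had 76.7 and 74.7% against 32.7 and 61.7% (exact McNemar test, adjusted p at most 1.02e-06). The 341 sites of RA replicate 1 alone had 31.7 and 39.9% against 29.0 and 28.7% at equal length. Only the 2 comparisons with MAML3 RA replicate 2 passed there (exact McNemar test, adjusted p = 0.338 and 0.188 for MAML3 RA replicate 1, and 0.000287 and 4.82e-05 for RA replicate 2). In the full lists all 4 comparisons passed, with 60.4% on each RA list against 29.0 and 53.1% (exact McNemar test, adjusted p at most 0.00525). These sites are not replicates, so the p-values describe these libraries. Of the 88 gained RARα sites on a MAML3 site of both RA libraries, 20 (22.7%) were on a gained MAML3 site. For RARα sites of both RA libraries that an untreated list also held, the number was 23 of 367 (6.27%, odds ratio 4.40, two-sided Fisher's exact p = 1.72e-05).

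**Figure D5:**
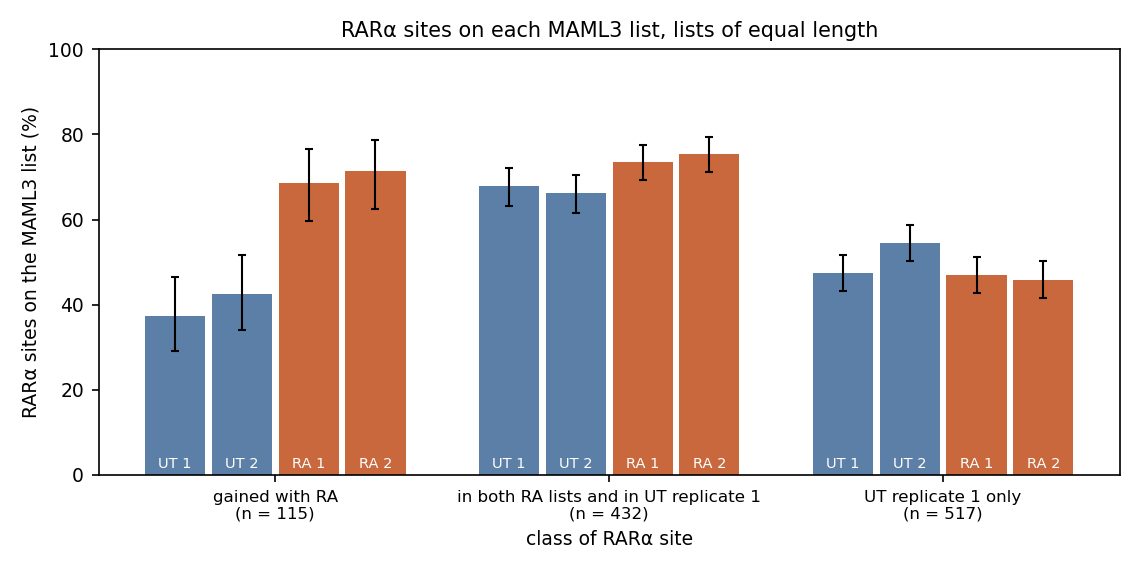
Percent of RARα sites of 3 classes (horizontal axis) that overlap each MAML3 list shortened to 2222 peaks (blue, untreated; orange, RA), with 95% Wilson intervals as error bars that cover counting error only. The 115 gained sites stand at 37.4 and 42.6% on the untreated lists and 68.7 and 71.3% on the RA lists, the 432 sites at 67.8 and 66.2% and at 73.6 and 75.5%, and the 517 sites of untreated replicate 1 alone at 45.8 to 54.5% on all 4.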

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

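Replicate overlap and the overlap of RARα with MAML3 kept their side of the threshold under the alternatives tested, 3 per group for the first (permutation p = 0.001, the smallest possible, in each). Relocated peaks or sites overlapped in at most 0.751% on average in these settings, so this outcome was all but fixed. It is no measure of how stable the shares are. Over 11 alternatives per treatment, 2 of them added after the data were seen, the share of RARα sites on MAML3 sites was 29.7 to 83.4% in untreated cells and 69.6 to 84.9% after RA. The order of the treatments was turned over sites in at least 1 replicate (83.4 and 81.8%), and the cause was not tested. With MAML3 lists of equal length the shares were 43.3 and 69.6%, and in the 50% of peaks with the highest score 29.7 and 71.5%. Replicate overlap was 90.7 to 95.9% (MAML3 UT), 78.6 to 83.0% (MAML3 RA), 74.5 to 81.0% (RARα UT) and 51.8 to 59.8% (RARα RA) under these 3. With lists of equal length, for which no p was computed, it was 73.4, 76.2, 43.4 and 62.2%, which puts RARα UT below RARα RA.

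Counts of gained and lost sites moved by more than 1.5 times under several alternatives. Main counts were 961 gained and 70 lost for MAML3, and 115 and 10 for RARα. In the top 50% of each list by score they were 501, 37, 74 and 6. In lists of equal length they were 289, 173, 45 and 17. For sites in the top 50% of both libraries and absent from the full lists of the other treatment they were 183, 23, 42 and 1. These settings hold fewer peaks by construction. The lost MAML3 sites were 39 when peaks within 1 kb were merged, since a neighbouring peak of an RA list then joins the site. With each replicate left out in turn, gained MAML3 sites were 981 to 3201, lost MAML3 sites 117 to 1370, gained RARα sites 125 to 463 and lost RARα sites 24 to 527, since 1 library then decides a group. The order of gained and lost was reversed without MAML3 UT replicate 1 (981 and 1370) and without RARα UT replicate 2 (125 and 527), the shortest list of each antibody. For the number of peaks per list, 8 values moved by construction in the top 50% by score, and 8 without chromosome Y did not. Leaving these out, 27 of the 70 alternative values were counts that moved by over 1.5 times. The other 43 were counts within that bound or overlap shares on the same side of the test, among them the untreated share of 29.7% against 56.1% in the main setting. No paired analysis was possible because the gained and lost counts come from no test, and shared replicate numbers carry no statement of a shared culture or day. Promoter shares, gene lists, motif shares and a relocation that keeps the distance to gene starts were not run. Unknown depth limits every count of sites absent from a list.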

Other observations

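All tests in the first 3 paragraphs here were chosen after the data were seen; those of the later paragraphs were set before their results were seen, except that the 2 settings with moved sites and without chromosome ends were added after the data were examined. RARα and MAML3 peaks were spread differently over the chromosomes. Chromosome 19 took 2.18% ± 0.34 of the RARα peaks and 0.404% ± 0.064 of the MAML3 peaks (SD, n = 4 libraries each), a ratio of 5.40 of the means. Chromosome 17 took 5.72% ± 2.60 against 2.57% ± 0.17, and chromosome X 3.93% ± 2.44 against 1.65% ± 0.074, a difference carried by the array described next. Chromosomes 13 (2.88 against 4.36%) and 18 (1.41 against 2.36%) went the other way. In each of these 5, as in chromosomes 1, 4, 5, 6 and 14, the 4 libraries of an antibody all lay above the 4 of the other (two-sided exact permutation p = 0.0286, the smallest possible), but none passed after adjustment over 23 chromosomes (adjusted p = 0.0657). Of the 2071 sites with a RARα peak, 330 touched no MAML3 list. Chromosome 19 held 35 of these 330 (10.6%) and 12 of the 1741 that did touch one (0.689%, two-sided Fisher's exact p = 2.09e-19). This chromosome was picked for its low MAML3 share, so the test is no separate evidence. Chromosome 1 held 10.3 and 9.82% (Fisher's exact p = 0.764), chromosome 17 held 6.36 and 3.68% (p = 0.0328, Fisher's exact test), and chromosome X 3.03 and 1.90% (p = 0.204, Fisher's exact test), with no adjustment over these 4. Examples of RARα sites without MAML3 were those on chromosome 17 at 45973185 to 45973721, on chromosome 19 at 14117150 to 14117522 and 6425012 to 6425499, and on chromosome 1 at 154955550 to 154955982, each in all 4 RARα lists.

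On chromosome X, RARα peaks formed a regular array between 114960310 and 115004810. It held 16 RARα sites, 15 of them in all 4 lists, at a median spacing of 2976 bp (quartiles 2958.5 and 3004). Of the 16, 13 touched a MAML3 list. In RARα UT replicate 2, the list of 251 peaks, the array gave 16 of the 19 peaks on chromosome X, and in the other RARα lists 15 or 16 of 30 to 33. The MAML3 lists had 5 to 11 peaks there, of 35 to 127 on the chromosome. Outside the array chromosome X took 1.15 to 1.56% of the peaks in the 4 RARα lists and 1.31 to 1.65% in the 4 MAML3 lists, so the higher RARα share of this chromosome was not seen there. MAML3 peaks stood close together elsewhere too: 14.2 to 18.2% of the gaps between neighbouring peaks were at most 10 kb, against 0.842 to 2.75% on average for relocated peaks. In the RARα lists, with the array included, the shares were 8.94 to 13.6% against 0.0965 to 0.489%. Dense MAML3 regions lay on chromosome 5 from 168196999 to 168431199 (15 sites in at least 3 lists), chromosome 1 from 216621500 to 216931849 (13 sites) and chromosome 4 from 41717199 to 41886679 (11 sites). In a further one on chromosome 4, from 151128049 to 151496511, MAML3 UT replicate 1 had 0 peaks while UT replicate 2 had 14 and the RA lists 16 each.

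Gained sites lay near each other more often than other sites. Of the 961 gained MAML3 sites, 492 (51.2%) had another within 500 kb, against a mean of 44.9% and a maximum of 502 sites in 1000 draws of as many sites from those in 2 of the 4 lists, gained ones included (one-sided permutation p = 0.002). For the 115 gained RARα sites the share was 17.4% against 9.55% (one-sided permutation p = 0.029). Another cluster of gained RARα sites, on chromosome 21 from 23122482 to 23189456, had 3 RARα peaks in each RA list and 0 in both untreated lists. The choice of the window by its 3 gained sites all but fixed these counts. The MAML3 lists held 3 and 4 peaks there after RA and 1 and 2 in untreated cells.

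The first pattern weighed was the excess of gained over lost MAML3 sites. In the full lists the ratio was 13.7, and without untreated replicate 1 fewer sites were gained (981) than lost (1370). With lists of equal length it was 1.67 (95% exact interval 1.38 to 2.03). The interval covers counting error only and takes sites as independent, not the spread between libraries. Most of the excess was absent there, but equal lengths draw gained and lost counts together by construction, also if RA adds sites. The fall from 13.7 therefore cannot show that the short untreated list made the excess. The interval also spans the bound of 1.5 set beforehand, so the prediction was not decided. At equal length the ratio depends on how far the 2 lists of each treatment agree. The RA pair shared 76.2% and the untreated pair 73.4% there. The ratio of 1.67 therefore cannot show whether RA adds sites. An effect of RA on MAML3 positions stays open: at equal length the treatments were parted by 462 sites, 2.51 times the 184 of the next split, which is also the split by lane number. The 2 untreated lists may be 1 library, which would raise the count of the treatment split over the others. Peak edges also differed between the untreated and RA lists, which these counts do not separate from the treatment. The 3 splits are too few for a share under 0.05.

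The second pattern was the overlap of RARα with MAML3 sites. With RARα sites moved by 10 to 100 kb, the highest share in any draw was 0.0381 of the observed one. A low share was bound to follow, since MAML3 sites fill little of even dense regions (15 sites in 124 kb of chromosome 4). Density at that scale alone therefore does not give the overlap, and grouping closer than 10 kb was not tested. Without the outer 100 kb of chromosomes, 178 of the 187 untreated and 547 of the 556 RA RARα sites remained. The share was then at least 1.01 times the observed one, an outcome that these counts all but fixed. The ends hold too few RARα sites to carry the overlap. The share of MAML3 sites with a RARα site rose from the lowest to the highest class of MAML3 score. It went from 2.89 to 10.1% in untreated cells and from 1.29 to 28.7% after RA. Positions that yield peaks with any antibody would give such a rise, which was part of the prediction set beforehand, and remain a candidate explanation. The score percentiles of the antibodies over shared sites correlated at rho = -0.126 in untreated cells (r = -0.150, permutation p = 0.2 and 0.12, 105 sites) and at rho = 0.199 after RA (r = 0.016, p = 1e-05, the smallest possible, and 0.73, 454 sites), which leaves it open, and the input samples were not analysed here.

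The third pattern was that RARα sites gained with RA coincided with MAML3 after RA more than before. Shorter untreated MAML3 lists would give equal shares once lists are of equal length, but the mean share on the RA lists was then 1.64 times that on untreated replicate 2, and both exact McNemar tests passed. Equal length does not equalise read depth, so shallower untreated libraries, also named in the prediction, were not tested by this. The 432 RARα sites also held by untreated replicate 1 lay more often on the RA lists too at equal length, but in the full lists no difference from untreated replicate 2 was detected (exact McNemar test, adjusted p = 0.204 and 0.284). In the full lists, RARα sites of RA replicate 2 alone had 76.7 and 74.7% against 61.7% on untreated replicate 2. Those of RA replicate 1 alone had 60.4% on each RA list against 53.1%. The pattern was thus not particular to gained sites. Sites of untreated replicate 1 alone went the other way, with 79.1 and 77.0% against 81.6%. Whether these classes differ was not tested. An effect of RA, a shared batch of the RA libraries, a difference in read depth and the differently resolved peak edges of the MAML3 RA lists all stay open. No test here parts them.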
